A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

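Poly(A)-selected RNA of rice seedlings (Oryza sativa, cultivar Nipponbare, 14 days old) was sequenced from 3 libraries of wild type (WT) and 3 of the mutant osino80-2, called osino80 here. Per the labels' protocols, plants grew in chambers without treatment, RNA was extracted with a column kit, and libraries were made with the KAPA stranded mRNA-seq kit. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

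The authors deposited a table of raw counts per gene and a table of TPM (transcripts per 1000000). Cutadapt, HISAT2, SAMtools and featureCounts were used, per the submitters' processing notes. Tool versions, the genome build, the annotation, the treatment of multi-mapping reads, the strand setting of the counting and the way TPM was computed are not given in the sources used here. The deposited counts are whole numbers for 55801 loci, and the deposited TPM columns sum to 1000000 each. Counts totalled 61426662 to 73293481 per library. In each library 82.4% to 83.7% of the counts between 1 and 20 were even, the excess that arises when both reads of a pair are counted; the number of sequenced fragments behind a count is then lower than the count, and counting intervals, which cover counting error only, are too narrow. The TPM table holds 665 loci above 0 that have 0 counts in all 6 libraries and 732 loci the other way round, so it was not made by rescaling the count table.

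Loci carry identifiers of the LOC_Os form, which the files do not pair with names. The reference table of rice genes (assembly ASM3414082v1) pairs 0 of them with a symbol. Gene names therefore come from 16 lists of published rice locus numbers, written from general knowledge before the data were examined; 109 of their 111 entries are in the files. As a check, names were looked up among the reference table's symbols and synonyms. The table placed 75 names on the chromosome that the locus number gives, and all 322 pairs of these that share a chromosome stood in the same order in both. It placed 3 names (CYP76M7, IRO2 and TOM1) on another chromosome, 2 matched several genes, and 31, OsINO80 among them, were not found. OsINO80 is taken as LOC_Os03g22900; the condition set beforehand, that an annotation name it so, could not be tested. A further 28 lists defined by words in gene descriptions were not run, because no descriptions were at hand. No coordinates are given for lack of an annotation of the build used.

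Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust=TRUE and glmQLFTest for genotype over all 6 libraries, two-sided, with Benjamini-Hochberg adjustment over the 24914 genes tested and a threshold of 0.05. "edgeR adjusted p" below means this test. CPM values (counts per 1000000) are TMM-scaled, given as mean ± SD over 3 libraries. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Lists with at least 3 tested members (14 of 16) were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated one; fry tests whether a list's genes move one way on balance without comparing them with other genes. On simulated counts for this comparison (24855 genes, the dispersion fitted to these libraries), the gene test recovered 43.3% of 67 genes changed 1.2-fold, 79.1% of 67 changed 1.5-fold and 98.5% of 66 changed 2-fold, with 9 false calls among 156; the list test called only the 1 list of 14 that had been changed. The simulation used 1 dispersion for all genes and understates the spread at low counts, so recovery there is overstated. At high counts it overstates the spread, so recovery there is understated. Its genes were drawn independently and few were changed, so its false calls are no measure of those in the real data.

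Genes named in the text follow a rule fixed beforehand: OsINO80, and up to 4 tested members with the smallest p in each list. The rule also takes, without an annotation, the 10 loci with the largest rise and the 10 with the largest fall among those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups; 2 of each are printed by identifier. Other list members mentioned were chosen after their values were seen. Alternatives fixed beforehand were the replicate number as a block, median-of-ratios and upper-quartile scaling, no low-count filter, a mean count of at least 10, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1) and log2(TPM + 0.1), robust=FALSE, and each library left out in turn. Halved counts, counts thinned to 10% and leaving out the loci with conflicting names were added after the data were seen. Same-numbered libraries did not deviate together (correlations of 0.0093, -0.029 and 0.0016), so the numbers were not treated as pairs. No 2 libraries agreed within sampling noise: the chi-square per gene was 3.60 to 4.03 in the 6 within-group pairs. Sampling noise gives 1 for independent counts and about 2 where both reads of a pair are counted. The check cannot tell separate plants from technical replicates, because noise from making the libraries was not measured and could also raise the value.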

Results

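Gene expression was compared between 14-day-old seedlings of wild-type Nipponbare rice and of osino80, a mutant of OsINO80, the ATPase of the INO80 chromatin remodelling complex, with 3 libraries per genotype. Total counts were 73293481, 69616322 and 61426662 in WT replicates 1 to 3 and 62239760, 61881971 and 66097710 in osino80 replicates 1 to 3. Of 55801 loci, 34517 had a count in at least 1 library and 24914 were tested. The 10 most abundant loci took 8.24% to 8.53% of the counts in each library, and TMM factors lay between 0.996 and 1.004. The lowest Pearson correlation of log2 CPM across genes within a genotype was 0.988 and the highest between genotypes was 0.968; genes are not independent replicates. The first principal component held 62.3% of the variance.

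The transcript of OsINO80, taken as LOC_Os03g22900 from its published locus number without an annotation to check it, was lower in the mutant. It had 8671, 8074 and 7404 counts in the WT libraries and 3731, 3792 and 4034 in the osino80 libraries. These correspond to 119 ± 2.43 CPM in WT and 60.6 ± 0.606 CPM in osino80 (SD, n = 3), a log2 fold change of -0.97 ± 0.03 (SE, edgeR adjusted p = 2.56e-115). The remaining transcript was 0.511 of the WT level.

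The comparison of genotypes asks which transcripts differ when OsINO80 is mutated. In osino80 seedlings 9 of 11 tested genes of diterpenoid phytoalexin synthesis were lower, with a median log2 fold change of -1.13 over the list. KAO, a gene of gibberellin biosynthesis, was 3.18-fold higher, at 59.3 ± 1.67 against 18.6 ± 0.191 CPM (SD, n = 3). Among stress markers, the cold-inducible genes DREB1A and DREB1B were 4.93-fold and 7.86-fold higher, while RAB16A and LEA3 fell to 0.264 and 0.179 of their WT levels. Flowering and clock regulators changed by less than 1.5-fold where they passed the test. In all, 4596 genes were higher and 4767 lower, together 37.6% of those tested. Most differences were small: the median absolute log2 fold change of the changed genes was 0.27, and 80.5% of them changed by less than 1.5-fold. Changes of at least 2-fold were found in 936 genes, of which 605 rose and 331 fell. The groups did not overlap in 45.7% of all tested genes, where chance gives 10% for 3 against 3. The median log2 fold change over all tested genes was 0.00. The common dispersion, a single value for all tested genes, corresponded to a coefficient of variation of 4.96% between libraries of a genotype. Abundant genes varied less than that: in WT the clock genes GI and LHY had 770 ± 6.47 and 630 ± 7.30 CPM (SD, n = 3). The small differences pass the test only against the spread between these libraries, which may be technical. All 896 genes past 2-fold that had a finite TPM ratio moved in the same direction in the deposited TPM.

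**Figure D1:**
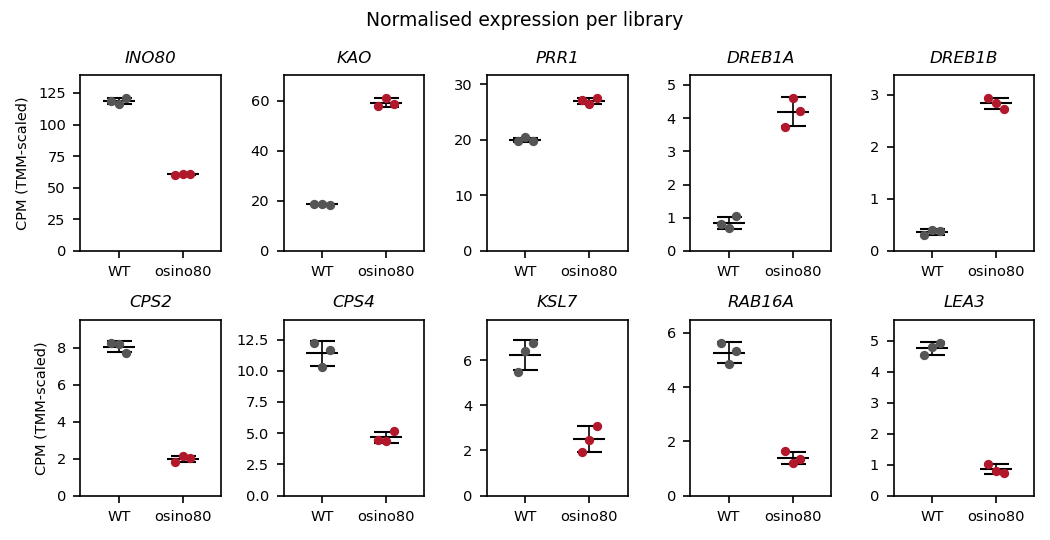
TMM-scaled CPM (vertical axes, from 0) of 10 genes in the 3 WT and 3 osino80 libraries; points are libraries, long bars the mean and capped bars the SD. In each of the 10 genes the 3 osino80 libraries lie outside the range of the 3 WT libraries, for example 60.6 against 119 CPM on average for INO80.

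Each of the 10 loci with the largest rise by the rule for named genes had at most 0.0688 CPM in WT. Of the 10 with the largest fall, 2 were close to silent in osino80, while the other 8 fell 4.72-fold to 8.69-fold and kept 1.75 to 47.6 CPM. LOC_Os04g34500 had 0 counts in each WT library and 844, 870 and 1013 counts in osino80, at least 976-fold higher against a floor of 3 counts over the WT group (edgeR adjusted p = 2.14e-147). LOC_Os10g18090 had 1 count in the WT libraries together and 3147, 3221 and 3354 counts in osino80, a ratio of 10443 with an exact 95% counting interval of 1874 to 412539. That count was in WT replicate 1, and without this library the locus was at least 2233-fold higher against the same floor. Conversely, LOC_Os11g09590 fell from 4333, 4117 and 3604 counts in WT to 2, 0 and 0 in osino80, a ratio of 5611 (1553 to 46334). Without osino80 replicate 1, which held those 2 counts, it was at least 2517-fold lower against a floor of 3 counts over the osino80 group. LOC_Os10g22630 fell from 434 ± 4.01 CPM in WT to 0.125 ± 0.0529 CPM in osino80 (n = 3). In all, 30 tested loci had at most 30 counts over one genotype and at least 100 in every library of the other, and 25 of these were on in osino80 and 5 off.

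Genes of diterpenoid phytoalexin synthesis, the enzymes that make momilactones, phytocassanes and oryzalexins, were lower in osino80. Of 11 tested members 9 fell, 7 of them at least 2-fold, and none rose. All 7 have locus numbers between LOC_Os02g36070 and LOC_Os02g36210 or between LOC_Os04g09900 and LOC_Os04g10160, so they are not 7 independent loci. The second stretch did not fall as a block: within it CYP99A3 (LOC_Os04g09920) at -0.08 ± 0.27 on the log2 scale did not pass. CYP99A2 (LOC_Os04g10160), at its end, changed by -0.50 ± 0.20. Outside these stretches KSL10 changed by -0.62 ± 0.25 on the log2 scale, and KSL8 at -0.23 ± 0.13 did not pass. CPS2, a copalyl diphosphate synthase that opens the phytocassane branch, fell from 8.07 ± 0.305 to 2.00 ± 0.162 CPM, a log2 fold change of -2.01 ± 0.13 (edgeR adjusted p = 3.57e-41). CPS4, which opens the momilactone branch, had 11.4 ± 1.02 CPM in WT and 4.69 ± 0.446 in osino80, a log2 fold change of -1.28 ± 0.10. The terpene synthase gene KSL7 changed by -1.31 ± 0.14 on the log2 scale and the cytochrome P450 gene CYP76M7 (LOC_Os02g36110) by -1.13 ± 0.16. The reference table places the name CYP76M7 on another chromosome; without that locus 8 of 10 members fell. CYP76M7 and CYP76M8 are similar copies, so their reads may have been split. The median log2 fold change of the list was -1.13, and camera placed it below the other genes (adjusted p = 8.33e-05). The call was lost in the camera run with an estimated correlation (adjusted p = 0.179, unadjusted p = 0.0128). That estimate was 0.0150 for this list, close to the preset 0.01, so the loss cannot be put down to correlation between members. The fry adjusted p of 0.000499 did not single out this list, as gibberellin biosynthesis had 0.000102 with fry. Only the brassinosteroid (0.405), clock (0.435), phosphate (0.104) and nitrogen (0.332) lists did not pass fry.

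Among 5 defence markers 3 fell, and none rose with adjustment over all genes. PR1a, a pathogenesis-related protein gene, fell from 1.13 ± 0.131 to 0.389 ± 0.0843 CPM (log2 fold change -1.53 ± 0.33, edgeR adjusted p = 3.10e-05). WRKY45, a transcription factor of salicylate signalling, changed by -0.32 ± 0.06 and PBZ1, a PR10 protein gene, by -0.14 ± 0.04 on the log2 scale. NH1, the rice NPR1 homologue, had a log2 fold change of 0.17 ± 0.08; it passed with adjustment over the list alone and, over all genes, only without WT replicate 2 (edgeR adjusted p = 0.0325, range over its alternatives 0.0325 to 0.392). The list did not stand apart from other genes (camera adjusted p = 0.444). Both allene oxide synthase genes of jasmonate synthesis were slightly higher, AOS1 by 0.24 ± 0.09 and AOS2 by 0.21 ± 0.09 on the log2 scale. Both calls were lost on TPM, that of AOS2 also with DESeq2, without the low-count filter and with robust=FALSE. AOS1 also lost its call without WT replicate 1 (edgeR adjusted p = 0.0982), WT replicate 2 (0.0936) or osino80 replicate 1 (0.197), in a range of 0.00778 to 0.197 over its alternatives. AOS2 lost it without WT replicate 2 (edgeR adjusted p = 0.188), WT replicate 3 (0.0631) or osino80 replicate 3 (0.326), in a range of 0.0388 to 0.326.

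Drought, cold and abscisic acid markers moved in both directions, with 4 of 9 higher, 4 lower and 1 not passing. The cold-inducible transcription factor genes DREB1B and DREB1A rose most. DREB1B rose from 0.360 ± 0.0528 to 2.83 ± 0.105 CPM, a 7.86-fold change (log2 fold change 2.97 ± 0.24, edgeR adjusted p = 8.21e-28). DREB1A rose 4.93-fold, from 0.853 ± 0.180 to 4.19 ± 0.433 CPM (edgeR adjusted p = 3.82e-29). In contrast, the late embryogenesis abundant protein gene LEA3 fell from 4.75 ± 0.207 to 0.852 ± 0.154 CPM (log2 fold change -2.48 ± 0.18, edgeR adjusted p = 2.10e-35). The dehydrin gene RAB16A fell from 5.27 ± 0.397 to 1.39 ± 0.227 CPM (log2 fold change -1.92 ± 0.16). As members went both ways, the list as a whole did not stand apart (camera adjusted p = 0.848).

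Of 7 tested genes of gibberellin biosynthesis 3 rose, 4 did not pass and none fell. KAO, which encodes ent-kaurenoic acid oxidase, rose 3.18-fold, from 18.6 ± 0.191 CPM in WT to 59.3 ± 1.67 CPM in osino80 (log2 fold change 1.67 ± 0.05, edgeR adjusted p = 1.12e-132). The tested locus numbered next to it, LOC_Os06g02010, chosen after its values were seen, had 10, 12 and 7 counts in WT and 141, 121 and 138 in osino80. GA20ox1, a gibberellin 20-oxidase gene, changed by 0.20 ± 0.06 and KS1, the ent-kaurene synthase gene, by 0.13 ± 0.05 on the log2 scale. KO2, the ent-kaurene oxidase gene, had a log2 fold change of -0.07 ± 0.05 and did not pass. Of members chosen after their values were seen, CPS1 had a log2 fold change of 0.04 ± 0.08, GA20ox2 of -0.00 ± 0.13 and GA3ox2 of 0.29 ± 0.20, none of which passed. The biosynthesis list did not pass camera (adjusted p = 0.134). The GA20ox1 call was lost without WT replicate 1 (edgeR adjusted p = 0.0853, range over its alternatives 0.00643 to 0.0853). That of KS1 was lost without WT replicate 1 (edgeR adjusted p = 0.209), WT replicate 2 (0.0548) or osino80 replicate 1 (0.364), with DESeq2, on TPM and without the low-count filter, in a range of 0.0125 to 0.364.

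Of 5 tested genes of gibberellin inactivation 1 rose. GA2ox4, a gibberellin 2-oxidase gene, went from 0.214 ± 0.109 to 0.618 ± 0.160 CPM in osino80 (log2 fold change 1.49 ± 0.46, edgeR adjusted p = 0.00448), a call lost without WT replicate 3 (0.0505, range over its alternatives 0.00262 to 0.0505). GA2ox1 at 0.61 ± 0.44, EUI1 at 0.36 ± 0.37 and GA2ox3 at 0.19 ± 0.09 on the log2 scale did not pass, although GA2ox3 did without WT replicate 3 (edgeR adjusted p = 0.0471, range 0.0471 to 0.898). All 3 genes of gibberellin signalling passed with small changes, 2 higher and 1 lower: the receptor gene GID1 by 0.11 ± 0.03, the F-box gene GID2 by 0.06 ± 0.02 and the DELLA repressor gene SLR1 by -0.07 ± 0.02 on the log2 scale. GID1 lost its call without osino80 replicate 2 (edgeR adjusted p = 0.103, range over its alternatives 0.00475 to 0.784). GID2 lost it without WT replicate 3 (edgeR adjusted p = 0.207), osino80 replicate 1 (0.195) or osino80 replicate 3 (0.0836), with DESeq2 and on TPM, in a range of 0.00173 to 0.433, and SLR1 on TPM, in a range of 0.0108 to 0.162. Neither list stood apart from other genes (camera adjusted p = 0.547 for inactivation and 0.848 for signalling).

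In the brassinosteroid list 2 of 7 tested genes rose and 1 fell. BZR1, a transcription factor of the pathway, rose by 0.47 ± 0.07 (edgeR adjusted p = 1.87e-10) and DWARF4, a biosynthetic P450 gene, by 0.24 ± 0.07, while the receptor gene BRI1 changed by -0.12 ± 0.03 on the log2 scale. D2 did not pass at -0.16 ± 0.08. The DWARF4 call was lost without WT replicate 1 (edgeR adjusted p = 0.131, range over its alternatives 0.00197 to 0.131) and on TPM. Camera gave an adjusted p of 0.848 for this list.

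Regulators of photoperiodic flowering changed little. Of 16 tested genes 4 rose, 1 fell and 11 did not pass. MADS56, a MADS-box repressor of flowering under long days, rose by 0.37 ± 0.04 (edgeR adjusted p = 1.26e-14), the CONSTANS-like gene COL4 by 0.16 ± 0.02 and the phytochrome gene PHYA by 0.14 ± 0.03, while PHYB changed by -0.16 ± 0.03 on the log2 scale. Hd3a, chosen after its values were seen, had 226 counts over the WT libraries and 178 over the osino80 libraries and did not pass. Ehd1, a promoter of flowering chosen likewise, had 2 and 10 counts, each in a single library, and was not tested. In the circadian clock list 2 of 12 genes rose, 3 fell and 7 did not pass. PRR1 rose by 0.43 ± 0.06 (edgeR adjusted p = 1.68e-12), whereas PRR37 changed by -0.21 ± 0.03, GI by -0.10 ± 0.02 and LHY by -0.10 ± 0.02 on the log2 scale. LHY had 630 ± 7.30 CPM in WT and GI 770 ± 6.47, so that changes of this size exceeded the spread between libraries. Camera gave adjusted p values of 0.444 for flowering and 0.996 for the clock.

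**Figure D2:**
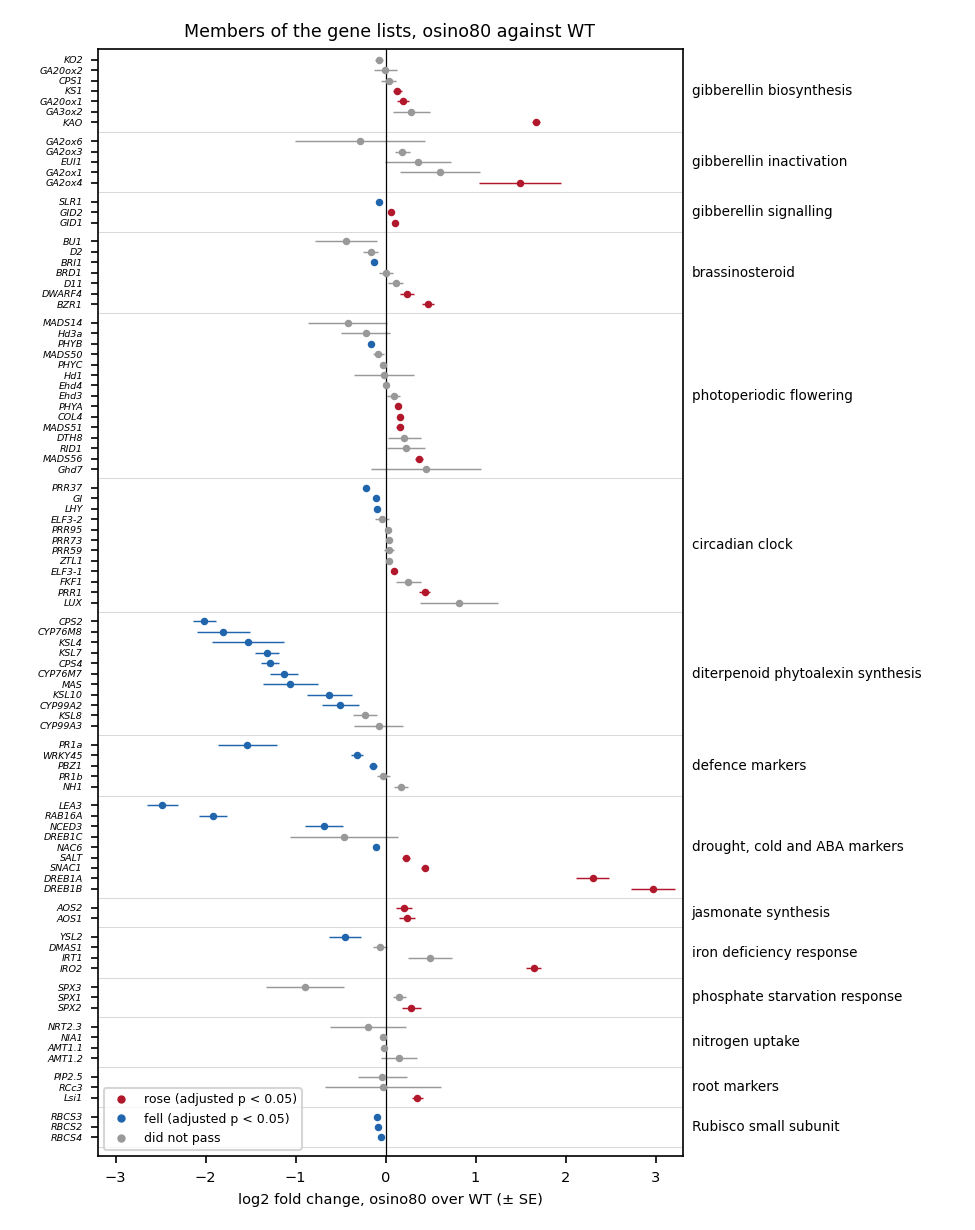
Log2 fold change of osino80 over WT (horizontal axis, with SE) for tested members of the gene lists, all but 1 of them drawn (vertical axis, grouped by list); red and blue mark genes that rose or fell at an edgeR adjusted p below 0.05, grey those that did not pass. The members of the phytoalexin list lie between -2.01 and -0.08, while the drought, cold and ABA list reaches from -2.48 to 2.97.

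In the iron deficiency list 4 of 9 genes were tested. LOC_Os01g72370, listed as IRO2, a bHLH regulator of iron uptake, rose 3.13-fold from 5.35 ± 0.313 to 16.8 ± 0.666 CPM (edgeR adjusted p = 1.61e-57); the reference table places that name on another chromosome. The transporter gene YSL2 changed by -0.45 ± 0.17 on the log2 scale, and lost its call without WT replicate 1 (edgeR adjusted p = 0.0522), WT replicate 3 (0.180), osino80 replicate 2 (0.0750) or osino80 replicate 3 (0.154), with DESeq2 and on TPM, in a range of 0.0171 to 0.462. IRT1 at 0.49 ± 0.25 and DMAS1 at -0.06 ± 0.08 did not pass, although IRT1 did without osino80 replicate 3 (edgeR adjusted p = 0.0307, range 0.0307 to 0.846). The median of the list was 0.22, and -0.06 without the locus listed as IRO2 (camera adjusted p = 0.444 and 0.890). Of 3 phosphate sensor genes, SPX2 rose by 0.29 ± 0.11, while SPX1 at 0.16 ± 0.07 and SPX3 at -0.90 ± 0.43 passed only with adjustment over the list alone. SPX2 lost its call without WT replicate 2 (edgeR adjusted p = 0.115), WT replicate 3 (0.0520) or osino80 replicate 1 (0.0816), in a range of 0.0147 to 0.115 over its alternatives. SPX1 gained one without osino80 replicate 3 (edgeR adjusted p = 0.0312) and with halved counts, in a range of 0.0312 to 0.336. None of the 4 tested members of the nitrogen list passed with edgeR, DESeq2 or limma voom, nor at an unadjusted edgeR p under 0.05. AMT1.1 had a log2 fold change of -0.01 ± 0.02, NIA1 of -0.03 ± 0.03, AMT1.2 of 0.15 ± 0.20 and NRT2.3 of -0.19 ± 0.42. Camera gave adjusted p values of 0.848 for the phosphate and 0.890 for the nitrogen list.

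The 3 tested Rubisco small subunit genes, abundant in green leaf, were lower: RBCS2 had 11218 ± 117 CPM in WT and 10558 ± 135 in osino80 (log2 fold change -0.09 ± 0.01, edgeR adjusted p = 2.69e-15), RBCS3 changed by -0.09 ± 0.01 and RBCS4 by -0.05 ± 0.01. These copies are near-identical, so the split of reads among them is uncertain. Camera called this list (adjusted p = 4.57e-06), but not with an estimated correlation (adjusted p = 0.210, unadjusted p = 0.0300) nor on TPM (adjusted p = 0.449 with a pseudocount of 1). For this list the estimate was 0.724, far above the preset 0.01, so the preset run took its members as more independent than they were. Over the 15 alternatives that kept the preset correlation and the full lists, the replicate block among them, its camera adjusted p ranged from 1.33e-12 to 0.449. Of 3 tested root markers, the silicon transporter gene Lsi1 rose by 0.35 ± 0.07 (edgeR adjusted p = 9.77e-07), and PIP2.5 at -0.04 ± 0.27 and RCc3 at -0.03 ± 0.64 did not pass (camera adjusted p = 0.548). The low-count filter left out 2 root markers: the silicon efflux transporter gene Lsi2 had 12, 14 and 8 counts in WT and 0 in each osino80 library, at least 10.6-fold lower against a floor of 3 counts over the osino80 group, and PIP2.3 had 30 counts over WT and 18 over osino80. Without the filter Lsi2, chosen after its values were seen, passed (edgeR adjusted p = 0.00154), and PIP2.3 did not (0.644). The shoot meristem markers were not tested: OSH1 had 0 counts in all 6 libraries, and OSH15 had 6 over the WT and 10 over the osino80 libraries.

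Of the 14 lists tested with camera, 2 passed with the preset correlation, those of phytoalexin synthesis and of the Rubisco small subunit. With an estimated correlation 0 passed, and 2 had an unadjusted p under 0.05. That estimate was 0.0150 for phytoalexin synthesis and 0.724 for the Rubisco small subunit. Counts of changed members adjusted over the list alone equalled those over all genes, except that 1 defence marker then rose and that 2 phosphate sensors rose and 1 fell. The sign of the median, the mean and the test differed within the circadian clock, the drought, cold and ABA, the phosphate and the root lists, none of which passed camera.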

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

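The counts halved, the counts thinned to 10% and the lists without conflicting names were tried after the data were seen. Under the alternatives fixed beforehand, 3767 to 4676 genes were higher and 3643 to 4773 lower, and none of the 9363 changed genes was called in the opposite direction under any setting run. Leaving out 1 library gave 4037 to 4159 higher and 4201 to 4356 lower, of which 572 to 655 and 315 to 342 by at least 2-fold. The scaling of the libraries moved the median log2 fold change by less than 0.01. Thinning to 10% of the depth left 2036 genes higher and 2041 lower, of which 236 and 154 by at least 2-fold, since fewer counts leave less power. On log2(TPM + 1), 187 genes were at least 2-fold higher and 89 lower, because the pseudocount shrinks the folds of weakly expressed genes. The number of lists past camera fell from 2 to 1 on log2(TPM + 1) and to 1 on log2(TPM + 0.1), where the Rubisco list was lost, and to 0 with an estimated correlation; the cause of the former was not tested. DESeq2, limma voom and robust=FALSE do not enter the list test, and 2 lists passed without the loci with conflicting names. With the replicate number as a block, 4556 genes were higher and 4773 lower, 9232 of the 9363 calls were kept, and all 58 other named genes kept their side of the threshold. The log2 fold change of OsINO80 lay between -0.98 and -0.94 under every alternative. Of 58 other named genes 41 kept their side of the threshold throughout; over all their alternatives 56 values lost the call, 5 gained one and 0 reversed. Depth limits small changes: thinning ended the call of 12 named genes. For BRI1 (edgeR adjusted p = 0.683) and PBZ1 (0.0695) thinning was the only alternative that did so.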

Other observations

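The tests of neighbouring genes, of genes low in WT, of on or off loci in the TPM table, of even counts and of the variance were chosen only after the result had been seen, at least in part. Genes changed at least 2-fold lay next to each other along the locus numbering more often than random sets. There were 88 adjacent pairs of tested genes that changed in the same direction, where 10000 random sets matched on mean expression gave a median of 21 and at most 42 (permutation p = 0.0001, the smallest they can give). In all, 161 of the 936 genes stood in such pairs or in runs of up to 4. The runs included a stretch of 4 genes with CYP76M8, CYP76M7 and KSL7 and a stretch of 3 with MAS and KSL4, all lower, and DREB1B, DREB1A and the locus between them, all higher. A candidate explanation is that neighbouring genes respond together; tandem copies that share reads could give the same pattern, and could not be examined without sequences.

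Of 4417 tested genes with a mean below 1 CPM in WT, 465 rose at least 2-fold, and of 4287 with a mean below 1 CPM in osino80, 236 had fallen at least 2-fold, an odds ratio of 2.02. As 3962 genes stand in both sets and the change itself decides which set a gene enters, whether genes close to silent in WT rose more often cannot be told apart from the overall excess of rises, 605 against 331.

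The genes around OsINO80 showed no detectable excess of large changes: 1 of the 40 flanking tested genes, 2.5% (exact 95% interval 0.0633 to 13.2), changed at least 2-fold, against 3.76% of all tested genes. At any size 17 of the 40 changed, against 37.6% of all tested genes. Too few genes were at hand to exclude a segment carrying changes with the mutation.

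The first pattern to follow up is the 30 loci that were on in one genotype and almost off in the other. Loss or gain of segments spanning several tested genes is argued against for most of them. Only 6.67% of them (2 of 30, exact 95% interval 0.818 to 22.1) lay within 5 tested genes of another. Random sets gave a median of 0 and a 95% limit of 2. The count misses neighbours that do not meet the same rule and segments of genes too weakly expressed to be tested. LOC_Os11g09200, LOC_Os11g09460 and LOC_Os11g09979, on in osino80, and LOC_Os11g09590, off, are numbered close together, so a segment differing between the lines stays open there. The counting step is argued against as well, since 96.7% (29 of 30) differed at least 8-fold in the same direction in the TPM table, although both tables may share alignments. Changes at single loci, whether from the mutation in OsINO80, from heritable chromatin states or from sequence differences between the plant lines, stay open and were not tested. For 5 of 30 (16.7%, exact 95% interval 5.64 to 34.7) a shared segment also stays open. These 5 lay beside a tested gene changed at least 2-fold in the same direction, 3 of them in runs of 3 genes. LOC_Os06g02010, beside KAO, was 1 of them.

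The second is that 605 genes rose and 331 fell by at least 2-fold. Low counts are argued against as the whole cause, since among genes with a mean log2 CPM of at least 2 the ratio was still 1.71 (101 against 59). Its exact 95% interval of 1.23 to 2.40 takes genes as independent. It is too narrow where neighbouring genes change together. Library scaling was not decided: the ratio over all genes was 1.83 and became 1.84 and 1.85 with median-of-ratios and upper-quartile scaling, but these moved the median log2 fold change by at most 0.0033 and could not have changed it. Scaling and a difference between the genotypes stay open.

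The third is the narrow spread between libraries of a genotype. The ratio of variance to mean, taken from medians over genes, was 3.19 to 3.90 in every range of counts from 10 to 10000 in both genotypes. The share of even counts among counts of 1 to 20 was at least 82.4% in every library, and counting both reads of a pair raises the ratio to about 2, so it bears on why the ratio exceeds 1 and not on the narrow spread. From counts of 10 to 20 to counts of 1000 to 3000 the ratio grew at most 1.098 times, so variation that scales with expression was small. Whether the libraries came from one pool or from several pools of many plants cannot be told apart, because both would keep the ratio flat and the labels do not give the source.

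The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 4596 genes higher, 4767 lower, 605 at least 2-fold higher and 331 at least 2-fold lower, and the highest number in any other split was 0 for each, with edgeR. At an unadjusted p under 0.05 the other splits called at most 362 genes and the real one 11121. Each other split mixes the genotypes, so their difference widens the spread within its groups and holds the calls down. The numbers from these splits are therefore no measure of what chance gives.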
